A study of Mus musculus with 36 samples.

How the data were processed

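Liver total RNA of male mice (36 samples, 6 in each of 6 groups of strain and diet) was treated with DNase, depleted of ribosomal RNA and sequenced as stranded paired-end libraries on an Illumina sequencer, per the labels' protocols. Each library was spread over 3 lanes, except C57BL/6J water replicate 4, for which 2 lane files were used here, giving 107 abundance files. Reads were aligned with HISAT to mm10 and abundances estimated with StringTie, per the submitters' processing notes; versions and the gene annotation are not given in the sources used here. The labels state that mice were assigned to diets at random and that each group held more mice than were sequenced, but not which animal gave which sample. P-values therefore measure the spread between these samples.

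Each deposited file lists 24421 gene symbols and unnamed assembled loci with coverage, FPKM and TPM, per the file headers. The deposited coverage is a signal per base, the deposited FPKM values are fragments per kilobase relative to library size, and the unnamed loci alone make up the full total of the TPM column, with the named genes listed on top of it, so that column was handled as a signal. The planned use of coverage summed over lanes was replaced, by the fallback fixed in advance, with the mean TPM of the lanes, because coverage was proportional to FPKM only for symbols with a single transcript. Symbols listed more than once in a file were summed. Every lane file correlated best with the other lanes of its own sample. The lane 8 file of FVB/NJ water replicate 9, with a named TPM sum of 512741 against 371087 and 374749 in its other lanes, was kept in the mean. Read counts are unknown; the implied gigabases come from the smallest ratio of FPKM to coverage in each lane file. Between 16023 and 17748 symbols were above 0 per sample.

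Libraries were scaled by the median of ratios over named genes, and values were analysed as log2(scaled TPM + 1), a scale that understates the change of weakly expressed genes. The 9748 genes with a mean scaled TPM of at least 1 were tested. limma 3.58.1 in R 4.3.3 fitted 1 mean per group with empirical Bayes moderation (trend and robust), and Benjamini-Hochberg adjusted p-values under 0.05 passed. Contrasts were fructose minus water in each strain, the 3 differences of these responses with a joint F test, their mean, and the 3 differences between strains on water, where counts over all genes also needed a log2 difference of at least 1 and counts of list members are given without it and with it. Of 45 gene lists, 36 with at least 5 measured members were tested with camera at a preset correlation of 0.01 and again with a correlation estimated by limma; the median, mean and test had the same sign in every list that passed. The lists, panel, contrasts and naming rule were fixed before the data were examined. A panel of 25 fructose and lipid genes was named in every strain, and Pnpla3 was not tested (mean 0.0657 scaled TPM).

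Genes were named by size of change within strains (up to 8 per direction, mean of at least 5 scaled TPM in the strain, no predicted-gene symbols). For the differences of response between strains they were also named by size (up to 5 per direction, same filters over all samples). In the joint test, the average and the water groups they were named by smallest p. Up to 4 members of each passing list were named as well. For the average response the rule was first read with the filters on symbol and level and then, after a first view, as written, without them. Nsdhl, Lss, Nr0b2, Cdh5 and Stab2, the water-group values of Fgf21 and Scd1, and the genes of FVB/NJ water replicate 2 were chosen after their values were seen. Some genes that the rule names are not reported here. Gene types and positions come from GENCODE M21. Libraries left out as standing apart (the 3 richest in ribosomal RNA and FVB/NJ water replicate 2), named genes scaled to a fixed total, the named share as a covariate, that lane 8 file not used and the shared sample numbers without the block were alternatives chosen after seeing the data. Other alternatives covered scaling, FPKM, summed coverage, pseudocount, filters, array weights, 1 lane, each strain fitted alone and each library left out.

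The fit was tested on simulated data of 9716 genes. For fructose minus water in C57BL/6J it recovered 50 of 67 genes changed by 0.5, 66 of 67 by 1 and 66 of 66 by 2 on the log2 scale, with 12 false among 194 calls. For C57BL/6J minus DBA/2J it recovered 35 of 67, 63 of 67 and 65 of 66, with 21 of 184 calls outside these genes. Those 21 may hold true calls, because 25 other genes were shifted by 0.5 in DBA/2J fructose and so differed in truth. In C57BL/6J the share of false calls was above the nominal one, and for the difference it was not determined. The list test was also tried on a simulated shifted list, which passed, and an unchanged one, which did not. The simulated genes varied independently and only 1 unchanged list was tried, so false passes from correlated genes could not show. With diets reassigned among the real samples, a median of 9, 6 and 11 lists passed at the preset correlation in C57BL/6J, DBA/2J and FVB/NJ. statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were also used.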

Results

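Liver RNA was profiled in male mice of 3 inbred strains, C57BL/6J, DBA/2J and FVB/NJ, after 14 weeks on drinking water with 8% (w/v) fructose or on plain water, begun at 7 weeks of age. Each of the 6 combinations of strain and diet held 6 samples, 36 in all. The question posed by the series title is whether genetically different mice respond differently to dietary fructose. The depth implied by the abundance files was 5.72 ± 0.982 gigabases per library (SD, n = 36), with a range of 3.80 to 8.69. The highest value, in FVB/NJ water replicate 9, came mostly from 1 lane that implied 6.46 gigabases, against 1.13 at most in its other lanes. That file also listed 95669 unnamed loci, against 47394 at most in the others, and whether it holds reads of 1 lane only is unknown. Fructose and water libraries differed in this depth by less than their spread in C57BL/6J (two-sided exact permutation p = 0.543), DBA/2J (exact permutation p = 0.909) and FVB/NJ (exact permutation p = 0.944).

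Libraries differed in how much of their signal fell on named genes. The named genes summed to 36.1% ± 7.33 (SD, n = 36) of the total of the assembled loci. Fructose minus water, this share differed by 5.23 points in C57BL/6J (exact permutation p = 0.26) and -5.85 in DBA/2J (exact permutation p = 0.253). In FVB/NJ the difference was -1.24 points (exact permutation p = 0.591). Rn45s, the precursor of ribosomal RNA, took 15.8% of the named signal in C57BL/6J water replicate 1, 13.5% in DBA/2J fructose replicate 10 and 4.49% in DBA/2J fructose replicate 11. The named share was 10.6%, 17.8% and 20.6% in those libraries. In the FVB/NJ water group, replicate 2 held the serum amyloid gene Saa1 at 14593 scaled TPM, against 38.4 ± 25.7 (SD, n = 5) in the other libraries of its group. These 4 libraries stood apart from the rest. The FVB/NJ libraries were run on lanes numbered 6 to 8 and the other strains on lanes 4 to 6, so for FVB/NJ against another strain the strain and the run cannot be told apart. Both diets of a strain were run on the same lane numbers.

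**Figure D1:**
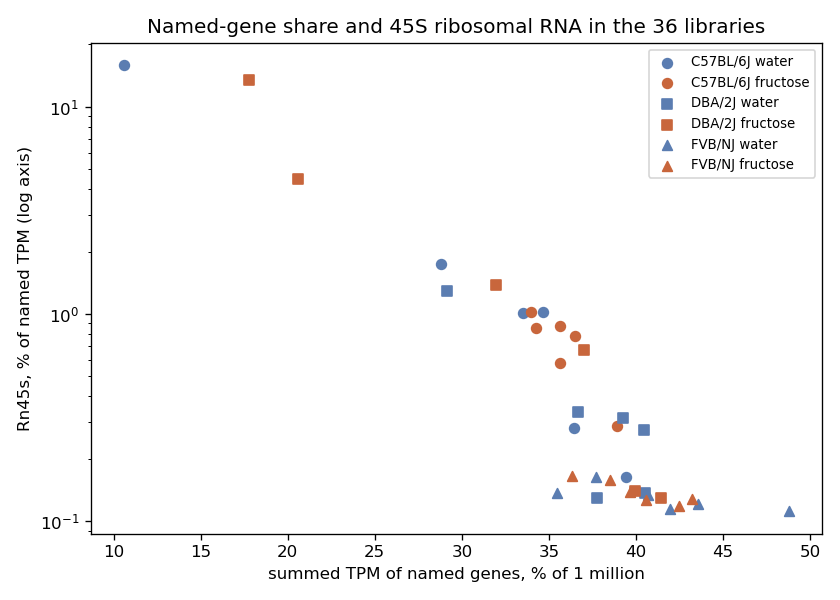
Summed TPM of named genes as a percentage of the TPM total of the assembled loci (horizontal axis) against Rn45s as a percentage of the named signal (vertical log axis) in the 36 libraries, with the marker shape giving the strain and the colour the diet. C57BL/6J water replicate 1 lies at 10.6% and 15.8%, and DBA/2J fructose replicate 10 at 17.8% and 13.5%.

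In C57BL/6J livers, genes of cholesterol synthesis fell with fructose. Idi1, which makes the isoprenoid unit dimethylallyl diphosphate, went from 18.3 ± 7.94 to 4.72 ± 2.37 scaled TPM (SD, n = 6 per group), a log2 fold change of -1.79 ± 0.28 (SE). The squalene epoxidase gene Sqle fell by 1.62 ± 0.24, Msmo1, a sterol demethylation enzyme, fell by 1.55 ± 0.24, and the lanosterol demethylase gene Cyp51 fell by 1.40 ± 0.20 on the log2 scale. Fdps, Hmgcs1 and Insig1, which encode farnesyl diphosphate synthase, the cytosolic HMG-CoA synthase and a sterol-regulated retention protein, fell by 1.39 ± 0.27, 1.06 ± 0.18 and 1.06 ± 0.22. Apoc2, the cofactor of lipoprotein lipase, rose from 146 ± 24.9 to 204 ± 33.3 scaled TPM (log2 fold change 0.48 ± 0.10).

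The list of cholesterol synthesis and uptake genes had 25 measured members, of which 13 fell, none rose and 12 did not pass. Adjusted over the list alone, 21 fell. Every member had a negative estimate, with a median log2 fold change of -0.62, and the list test gave an adjusted p of 8.23e-51, and adjusted p = 0.000891 with an estimated correlation. It was the single list in C57BL/6J that also passed with an estimated correlation. Further members that fell were Nsdhl (-1.01 ± 0.17) and Lss, the lanosterol synthase gene (-0.60 ± 0.10). The sterol transport gene Stard4 fell by 0.80 ± 0.18, a call that was lost without the 4 libraries that stood apart and in 36 of 55 alternatives in all.

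Other lists moved by smaller amounts in C57BL/6J. The nuclear-encoded respiratory chain list had a median of 0.10 over 37 genes, 35 of them positive, at adjusted p = 0.494 with an estimated correlation. None of its members passed over all genes with limma, 10 had an unadjusted p under 0.05, and 2 passed adjusted over the list alone (Cycs 0.36 and Sdhd 0.21). The fatty acid oxidation list was positive for 43 of 44 genes with a median of 0.16, at adjusted p = 0.494 with an estimated correlation, with 0 members passing over all genes or adjusted over the list alone in limma and 4 at an unadjusted p under 0.05. The TCA cycle list (median 0.15) and the periportal hepatocyte list (median 0.25) were both at adjusted p = 0.121 with an estimated correlation. Neither had a member passing over all genes with limma, 6 in each had an unadjusted p under 0.05, and adjusted over the list alone 3 and 2 were higher. The urea cycle (0.20) and gluconeogenesis (0.11) lists had adjusted p = 0.494 with an estimated correlation, and the interferon list (0.07) adjusted p = 0.646 with an estimated correlation.

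Towards lower expression in C57BL/6J were the lists of ribosomal proteins (median -0.06), extracellular matrix (-0.09), sex-biased genes (-0.17), endothelial (-0.08) and pericentral markers (-0.14), glutathione and NRF2 targets (-0.06), erythroid cells (-0.19), Cyp drug metabolism (-0.14) and bile acid synthesis (-0.12). They ranged from adjusted p = 0.346 to 0.607 with an estimated correlation, and 0 of their members passed over all genes with limma, against 1 to 5 per list at an unadjusted p under 0.05. Adjusted over the list alone, none was lower, and 1 gene of the bile acid list was higher, Nr0b2, a repressor of bile acid synthesis (1.22 ± 0.35, adjusted p 0.249 over all genes). The list of ChREBP targets, genes bound by a carbohydrate-sensing transcription factor, had a median of -0.03 over 23 genes, at adjusted p = 0.495 with an estimated correlation. It had 0 members passing over all genes with limma, 3 at an unadjusted p under 0.05, and 2 lower when adjusted over the list alone (Fasn and Tkfc). The fatty acid synthase gene Fasn stood at -0.67 ± 0.16 (adjusted p 0.0563) and Tkfc, the triokinase of fructolysis, at -0.58 ± 0.19 (adjusted p 0.361). With limma, 0 of the 24 tested genes of the fructose and lipid panel passed in C57BL/6J and 3 had an unadjusted p under 0.05, the estimates running from -0.69 (Cyp7a1) to 0.20 (Cpt1a).

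In all, 2 genes rose and 20 fell in C57BL/6J among the 9748 tested with limma, 657 had an unadjusted p under 0.05, and 18 of 36 lists passed with the preset correlation (7 higher, 11 lower). The other gene that rose, the read-through transcript Apoc4-apoc2 (0.37 ± 0.07), overlaps Apoc2 on chromosome 7 and its value is uncertain. Apoc2 lies at 19671579 to 19677941 on that chromosome, Idi1 at 8885606 to 8892396 on chromosome 13, Sqle at 59315092 to 59331193 on chromosome 15 and Msmo1 at 64718145 to 64733578 on chromosome 8, all in mm10. The count of genes was 11 without fructose replicate 13, 12 without fructose replicate 10 and 13 without water replicate 3, the library highest in cholesterol genes. A fit of the 12 C57BL/6J samples alone called 1 gene and array weights called 69. Scaling named genes to a fixed total gave 8 (3 higher, 5 lower), TPM without scaling gave 13 (10 higher, 3 lower, with the median of all genes shifted by 0.32), and FPKM without scaling gave 0, with 684 at an unadjusted p under 0.05.

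In DBA/2J livers, the lipid desaturase gene Scd1 and genes of the interferon response rose with fructose. Scd1, which makes monounsaturated fatty acids, rose from 68.7 ± 20.0 to 259 ± 85.9 scaled TPM (SD, n = 6 per group), a 3.67-fold change (log2 1.88 ± 0.34 SE, adjusted p 0.00219). Among interferon-induced genes, Ifit1 rose 2.18-fold (adjusted p 0.000929), Rtp4 rose 2.11-fold (adjusted p 0.000247) and Usp18, a negative regulator of interferon signalling, rose 2.09-fold (adjusted p 0.000297). Ifit3, the antiviral GTPase gene Mx2 and Rsad2 rose 1.97-fold, 1.95-fold and 1.90-fold. Pdk4, a kinase that restrains pyruvate oxidation, went from 20.3 ± 11.8 to 5.41 ± 1.68 scaled TPM (log2 -1.51 ± 0.32, adjusted p 0.0114).

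The interferon response list had 25 measured members in DBA/2J, of which 10 rose, none fell and 15 did not pass. Adjusted over the list alone, 16 rose. All 25 estimates were positive with a median of 0.39, and the list test gave an adjusted p of 1.8e-26, and adjusted p = 0.0391 with an estimated correlation. Oasl1 rose by 0.91 ± 0.13 and Xaf1 by 0.72 ± 0.11 on the log2 scale. The list of Kupffer cell and macrophage markers was positive for 14 of 15 genes with a median of 0.11, at adjusted p 0.0198 with the preset correlation and adjusted p = 0.616 with an estimated correlation. It had 0 members passing over all genes or adjusted over the list alone in limma, and 1 at an unadjusted p under 0.05. The MHC list (median 0.14), the endothelial list (0.05, with Cdh5 at 0.25 ± 0.07 and Stab2 at 0.46 ± 0.14 higher adjusted over the list alone) and the circadian clock list (0.13, with 3 higher and 1 lower adjusted over the list alone) also had adjusted p = 0.616 with an estimated correlation.

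Lists of oxidative metabolism moved towards lower expression in DBA/2J, each at adjusted p = 0.616 with an estimated correlation. In the fatty acid oxidation list, with 44 genes and a median of -0.16, Pdk4 fell over all genes and 3 genes were lower adjusted over the list alone. The hormone gene Fgf21 averaged 30.4 ± 9.28 with fructose and 86.9 ± 26.4 with water (log2 -1.49 ± 0.38, adjusted p 0.0559), a difference that passed without the 4 libraries that stood apart (-1.56). All 37 respiratory chain genes had negative estimates, with a median of -0.11, 0 passing over all genes with limma, 15 at an unadjusted p under 0.05, and 2 adjusted over the list alone. In the TCA cycle list (median -0.10), Dlst fell by 0.32 ± 0.08 and 2 genes were lower adjusted over the list alone. The cholesterol list had a median of -0.25 in DBA/2J, with 20 of 25 genes negative, 0 passing over all genes or adjusted over the list alone in limma, and 5 at an unadjusted p under 0.05. The lists of ribosomal proteins (-0.08), glutathione and NRF2 targets (-0.15) and the urea cycle (-0.13) were likewise at adjusted p = 0.616 with an estimated correlation, with 0 members passing over all genes with limma and 4, 4 and 6 at an unadjusted p under 0.05. Of the 24 panel genes, Scd1 alone passed in DBA/2J.

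Other genes that fell in DBA/2J were Moxd1, a monooxygenase-like gene (-2.28 ± 0.56), the ephrin receptor gene Epha2 (-1.05 ± 0.16), the ecto-nucleotidase gene Nt5e (-0.62 ± 0.10), Ccdc117 (-0.59 ± 0.14), Hacl1, an enzyme of peroxisomal alpha-oxidation (-0.57 ± 0.14) and the splicing factor gene Tra2b (-0.56 ± 0.12). The small nucleolar RNA Snora61 rose by 1.02 ± 0.25, and it lies within the host transcript Snhg12 on chromosome 4, so its value is uncertain. The calls of Snora61, Moxd1, Ccdc117 and Hacl1 were lost without the 4 libraries that stood apart. In all, 42 genes rose and 27 fell in DBA/2J, with 1184 at an unadjusted p under 0.05. With the preset correlation 12 of 36 lists passed, 5 higher and 7 lower, and 7 without the 3 libraries richest in ribosomal RNA. With an estimated correlation 1 list passed. The count of genes was 35 without fructose replicate 13, 37 without water replicate 4, 41 without fructose replicate 11 and 106 without FVB/NJ water replicate 2. It was 45 without those 3 libraries, 118 in a fit of the 12 DBA/2J samples alone and 354 with array weights. It was 31 (23 higher, 8 lower) with named genes scaled to a fixed total, 24 (5 higher, 19 lower) without scaling, where the median of all genes shifted by -0.22, and 11 (3 higher, 8 lower) from FPKM.

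In FVB/NJ livers, glutathione transferase and cytochrome P450 genes were among those that changed with fructose. Gstp1, which conjugates glutathione to electrophiles, rose from 516 ± 169 to 1076 ± 189 scaled TPM (SD, n = 6 per group), a 2.17-fold change (log2 1.12 ± 0.17 SE, adjusted p 0.00105). Its neighbour Gstp2 rose 2.16-fold and Gstm1 rose 1.66-fold. Mup20, a major urinary protein gene, rose 2.94-fold, from 332 ± 109 to 949 ± 263. The cytochrome P450 genes Cyp3a44 and Cyp3a11 rose 2.90-fold and 1.65-fold, while Cyp2b10, a target of the nuclear receptor CAR, fell by 1.82 ± 0.41 and Cyp2c70, which makes muricholic bile acids, fell by 1.44 ± 0.29 on the log2 scale. Without the 4 libraries that stood apart, the calls of Gstm1, Cyp3a44, Cyp2b10 and Cyp2c70 were lost.

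The glutathione and NRF2 target list had 29 measured members in FVB/NJ, of which 4 rose, none fell and 25 did not pass. Adjusted over the list alone, 15 rose. Its median was 0.38, with adjusted p = 0.284 with an estimated correlation against 3.27e-15 with the preset value, and Gstm4 rose by 0.67 ± 0.14. In FVB/NJ water replicate 2 the mean log2 level of this list was 4.80, against 5.43 in the next library of its group, and the list median was 0.30 without the 4 libraries that stood apart. The acute phase and complement list had a median of -0.47 over 38 genes, with 34 negative, at adjusted p = 0.425 with an estimated correlation, and -0.14 without those 4 libraries. With limma 0 of its members passed over all genes, 16 had an unadjusted p under 0.05, and 3 were lower adjusted over the list alone (C8b, Hp and Hc). The haptoglobin gene Hp stood at -0.92 ± 0.29 (adjusted p 0.12). In FVB/NJ water replicate 2, Hp measured 9106 scaled TPM against 1250.5 ± 239.9 (SD, n = 5) in the other libraries of its group.

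Lists of sugar handling and fat synthesis moved towards higher expression in FVB/NJ. In the de novo lipogenesis list, with 28 genes and a median of 0.18, 1 gene rose over all genes and 5 adjusted over the list alone, at adjusted p = 0.425 with an estimated correlation. The gene that rose was Acaca, the acetyl-CoA carboxylase of fatty acid synthesis (0.35 ± 0.09, adjusted p 0.0482), a call that was lost without the 4 libraries that stood apart and in 43 of 54 alternatives in all. Scd1 averaged 972 ± 303 with fructose and 559 ± 530 with water (log2 1.15 ± 0.34, adjusted p 0.102). In the fructose uptake and fructolysis list, with 14 genes and a median of 0.22, limma passed 0 over all genes, with 6 at an unadjusted p under 0.05 and 2 adjusted over the list alone (Aldh2 and Adh1), at adjusted p = 0.409 with an estimated correlation. The ketohexokinase gene Khk, the entry enzyme of fructolysis, stood at 0.42 ± 0.16 (adjusted p 0.232). The ChREBP target list had a median of 0.17 over 23 genes, with 2 that rose over all genes and 2 adjusted over the list alone, at adjusted p = 0.425 with an estimated correlation. Tkt, the transketolase gene of the pentose phosphate pathway, rose by 0.57 ± 0.11 (adjusted p 0.0131), and the glycolytic genes Gpi1 and Pfkm rose by 0.38 ± 0.07 and 0.62 ± 0.12. The lists of glycolysis (median 0.06, 2 rose), the pentose phosphate pathway (0.06, 1 rose), Cyp drug metabolism (0.22, 2 rose and 1 fell) and the respiratory chain (0.10, Sdhd rose) were at adjusted p = 0.425 with an estimated correlation. Of the 24 panel genes, Acaca alone passed in FVB/NJ, with that limit.

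Among lists that moved towards lower expression in FVB/NJ, the basement membrane collagen genes Col4a1 (-0.38 ± 0.09) and Col4a2 (-0.40 ± 0.10) fell in the extracellular matrix list (median -0.10, adjusted p = 0.523 with an estimated correlation). The chemokine gene Ccl9 (-0.53 ± 0.11) fell in the cytokine list (median -0.11, adjusted p = 0.425 with an estimated correlation). The lists of the unfolded protein response (-0.19), immediate early genes (-0.30) and the glucocorticoid and fasting response (-0.18) ran from adjusted p = 0.425 to 0.594 with an estimated correlation, with 0 members passing over all genes in limma and 3, 4 and 2 at an unadjusted p under 0.05. The fatty acid oxidation (0.11) and ribosomal protein (0.05) lists had adjusted p = 0.794 and 0.799 with an estimated correlation. The first had a median of -0.03 without the 4 libraries that stood apart, and the ribosomal list -0.01 after quantile normalization.

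Further genes that rose in FVB/NJ were Csad, of taurine synthesis (from 111 ± 48.8 to 208 ± 59.2 scaled TPM, SD, n = 6 per group), and the small Cajal body RNA Scarna10 (0.79 ± 0.19). Enho, the adropin gene (-0.95 ± 0.21), Gbp11 (-0.84 ± 0.20), the urate pathway gene Urad (-0.78 ± 0.19), Mir7225 (-0.64 ± 0.16), the coagulation factor gene F11 (-0.60 ± 0.12) and the murinoglobulin pseudogene Mug-ps1 (-0.60 ± 0.12) fell. Gstp1 and Gstp2, Gstm1 and Gstm4, Mup20, Cyp3a11 and Cyp3a44, Cyp2b10, Gbp11 and Mug-ps1 have close paralogs, and the share of reads each received is uncertain. In all, 44 genes rose and 37 fell in FVB/NJ, with 1329 at an unadjusted p under 0.05. Of 36 lists, 16 passed with the preset correlation (10 higher, 6 lower), 0 passed camera with an estimated one, where 3 had an unadjusted p under 0.05, and 6 passed without the 4 libraries that stood apart. The count of genes was 9 without fructose replicate 18, 29 without water replicate 2, 33 without fructose replicate 6, 164 without water replicate 1 and 24 without those 4 libraries, where the calls of Csad, Scarna10, Enho, Gbp11, Urad and Mir7225 were lost too. It was 1 in a fit of the 12 FVB/NJ samples alone, 27 with array weights, 27 (18 higher, 9 lower) with named genes scaled to a fixed total, 29 from 1 lane per sample, 9 (8 higher, 1 lower) without scaling and 5, all higher, from FPKM.

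**Figure D2:**
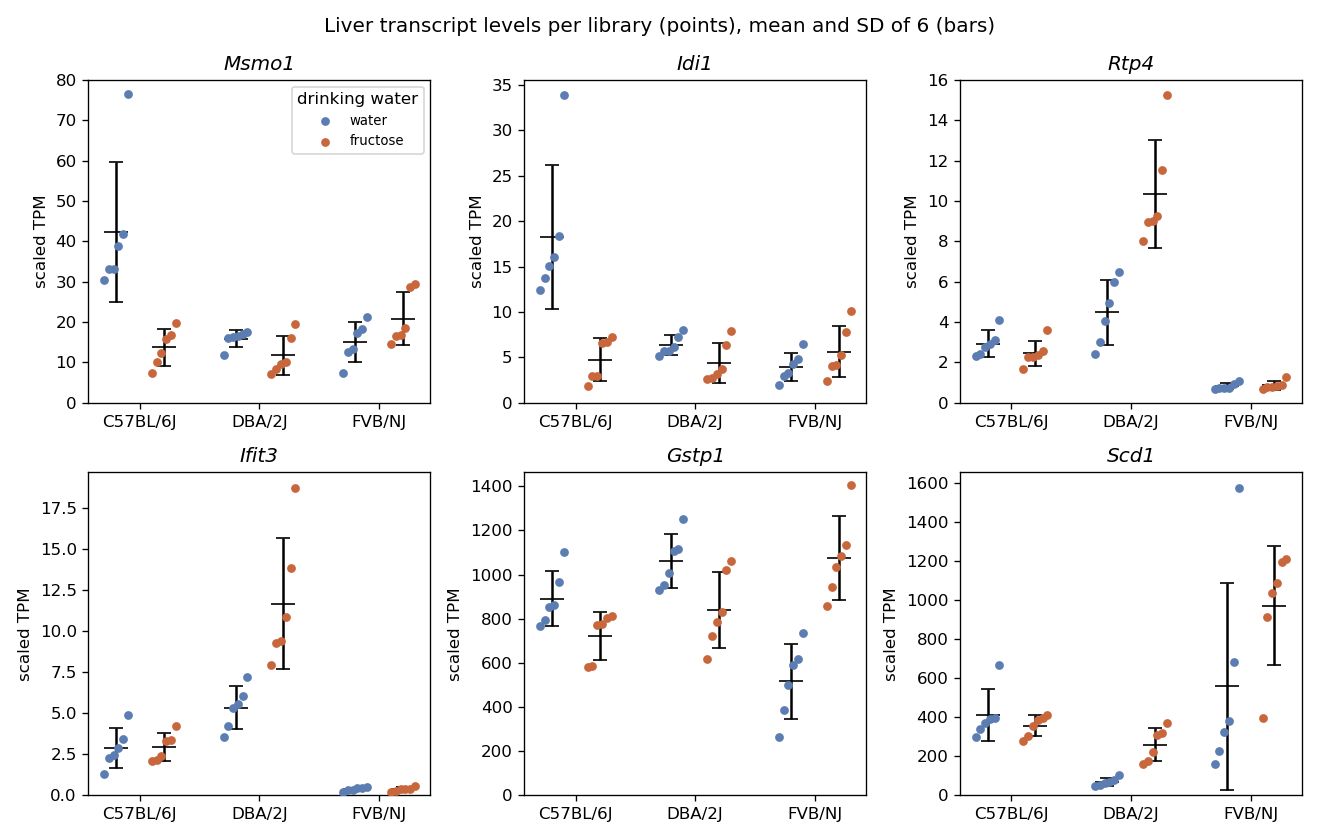
Scaled TPM (vertical axes, from 0) of 6 genes in each library (points) by strain and diet, with the mean and SD of 6 libraries (bars). In C57BL/6J Msmo1 averaged 42.4 with water and 13.7 with fructose, in DBA/2J Rtp4 averaged 4.48 and 10.4, and in FVB/NJ Gstp1 averaged 516 and 1076.

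The difference between strains was tested directly, as the fructose response of a strain minus that of another. For the cholesterol genes Idi1 and Msmo1, the response of C57BL/6J lay below that of FVB/NJ by log2 differences of -2.16 ± 0.40 (SE, adjusted p 0.00832) and -2.01 ± 0.34 (adjusted p 0.00336). For Gstp1, the response of FVB/NJ exceeded that of both other strains, with log2 differences of -1.42 ± 0.24 for C57BL/6J minus FVB/NJ (adjusted p 0.00336) and -1.47 ± 0.24 for DBA/2J minus FVB/NJ (adjusted p 0.00427). Scd1 responded less in C57BL/6J than in DBA/2J (-2.04 ± 0.49, adjusted p 0.0461), a call that was lost in 35 of 54 alternatives. The nuclease gene Trex1, which limits interferon induction, responded more in DBA/2J than in C57BL/6J (-0.66 ± 0.13 for C57BL/6J minus DBA/2J, adjusted p 0.0196) and FVB/NJ (0.67 ± 0.13, adjusted p 0.0116).

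Between C57BL/6J and DBA/2J, 28 genes had a higher and 18 a lower response in C57BL/6J, with 1263 at an unadjusted p under 0.05. The transferrin receptor gene Tfrc (1.19 ± 0.24), the transporter gene Slc16a5 (1.16 ± 0.27), Tra2b (0.98 ± 0.16) and Hacl1 (0.98 ± 0.20) were higher, and Snhg12 (-0.82 ± 0.18), Scpep1 (-0.53 ± 0.12) and Rassf8 (-0.44 ± 0.11) lower. Without scaling, which shifted the median of all genes by 0.54, Scpep1 stood at 0.09 and Rassf8 at 0.16, and 88 genes were called, 88 of them higher. Scaling named genes to a fixed total left 7 calls (6 higher, 1 lower), and quantile normalization gave 22 higher and 33 lower. Without the 4 libraries that stood apart the count was 8, and of the genes named for this pair, Scd1 and Trex1 included, Tra2b alone kept its call. That of Rassf8 was also lost without the lane file in doubt.

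Between C57BL/6J and FVB/NJ, 5 genes had a higher and 19 a lower response in C57BL/6J, with 1022 at an unadjusted p under 0.05. Urad (1.21 ± 0.26), the coat protein genes Sec13 (0.55 ± 0.12) and Copg1 (0.44 ± 0.10), Csad (-1.68 ± 0.36) and Gstp2 (-1.42 ± 0.24) were among them, and those 5 except Gstp2 lost the call without the 4 libraries that stood apart. Between DBA/2J and FVB/NJ, 21 were higher and 14 lower in DBA/2J, with 990 at an unadjusted p under 0.05. Apol9a (1.26 ± 0.27), Gbp11 (1.21 ± 0.28), Parp9 (0.56 ± 0.13) and the antiviral zinc finger gene Zc3hav1 (0.43 ± 0.10) were higher, and Mup20 (-1.60 ± 0.38), Gstp2 (-1.46 ± 0.24), Gstm4 (-1.03 ± 0.20) and Htatip2 (-0.82 ± 0.18) lower, of which Gbp11, Zc3hav1, Mup20 and Htatip2 lost the call without the 4 libraries that stood apart, and Gbp11 and Mup20 also without the lane file in doubt. The counts were 7 (6 higher, 1 lower) and 2 (0 higher, 2 lower) without scaling, where 512 and 312 genes had an unadjusted p under 0.05 with limma, and 10 (4 higher, 6 lower) and 4 (2 higher, 2 lower) with named genes scaled to a fixed total.

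Of the lists, cholesterol synthesis separated C57BL/6J from FVB/NJ, with a median difference of -0.70, 7 genes lower over all genes, 20 adjusted over the list alone, and adjusted p = 0.0408 with an estimated correlation. Against DBA/2J its median difference was -0.42, with 0 genes lower over all genes in limma, 13 at an unadjusted p under 0.05, 12 adjusted over the list alone, and adjusted p = 0.265 with an estimated correlation. The interferon list separated DBA/2J from FVB/NJ by a median of 0.52, with 7 genes higher over all genes, 13 adjusted over the list alone, and adjusted p = 0.0798 with an estimated correlation. For C57BL/6J minus DBA/2J its median was -0.32, with 4 genes lower over all genes, 9 adjusted over the list alone, and adjusted p = 0.269 with an estimated correlation. The glutathione list was lower by a median of -0.43 for C57BL/6J minus FVB/NJ (2 genes over all genes, 10 adjusted over the list alone, adjusted p = 0.184 with an estimated correlation) and by -0.60 for DBA/2J minus FVB/NJ (3 and 16 genes, adjusted p = 0.0798 with an estimated correlation).

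For the respiratory chain, all 37 genes had a lower estimate in DBA/2J than in C57BL/6J, with a median difference of 0.21, 1 gene passing over all genes, 16 adjusted over the list alone, and adjusted p = 0.269 with an estimated correlation. The fatty acid oxidation list differed in the same pair by a median of 0.32, with 0 genes passing over all genes in limma, 17 at an unadjusted p under 0.05, 6 adjusted over the list alone, and adjusted p = 0.465 with an estimated correlation. With the preset correlation 11, 12 and 21 of 36 lists passed for C57BL/6J minus DBA/2J, C57BL/6J minus FVB/NJ and DBA/2J minus FVB/NJ. With an estimated correlation camera passed 0, 1 and 0, and 5, 3 and 8 had an unadjusted p under 0.05.

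The joint test of strain by diet passed for 77 genes, with 1327 at an unadjusted p under 0.05. Among genes with a mean of at least 5 scaled TPM, the 10 with the smallest p were Gstp1, Gstp2, Tra2b, Trex1, Msmo1, Tkt, the ATP synthase subunit gene Atp5g3, Idi1, Gstm4 and the proteasome gene Psma5, with adjusted p from 0.00134 to 0.0174. Tra2b stood at 0.42 ± 0.12 (SE) in C57BL/6J and fell by 0.56 ± 0.12 in DBA/2J. The calls of the strains shared 0 genes in the same direction in every pair in limma, where independent lists would share at most 0.190 genes per pair and direction. Across the 9748 genes, which are not independent replicates, the log2 responses correlated at r = -0.10 (rho -0.18) for C57BL/6J and DBA/2J, -0.08 (rho -0.03) for C57BL/6J and FVB/NJ, and 0.15 (rho 0.17) for DBA/2J and FVB/NJ. Of 100 reassignments of diet within strains, the real one included, 52, 48 and 19 gave a Pearson r as large in size for these pairs and 22, 75 and 18 a rho as large.

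Single libraries decided how many genes passed these tests. The count ran from 6 without C57BL/6J fructose replicate 12 to 114 without FVB/NJ water replicate 2 for C57BL/6J against DBA/2J. It ran from 10 without C57BL/6J fructose replicate 13 to 86 without FVB/NJ water replicate 1 for C57BL/6J against FVB/NJ, and from 14 without DBA/2J water replicate 4 to 41 without FVB/NJ water replicate 1 for DBA/2J against FVB/NJ. For the joint test it ran from 25 without C57BL/6J fructose replicate 13 to 148 without C57BL/6J water replicate 6. Without the 4 libraries that stood apart the counts were 8, 14, 20 and 41.

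**Figure D3:**
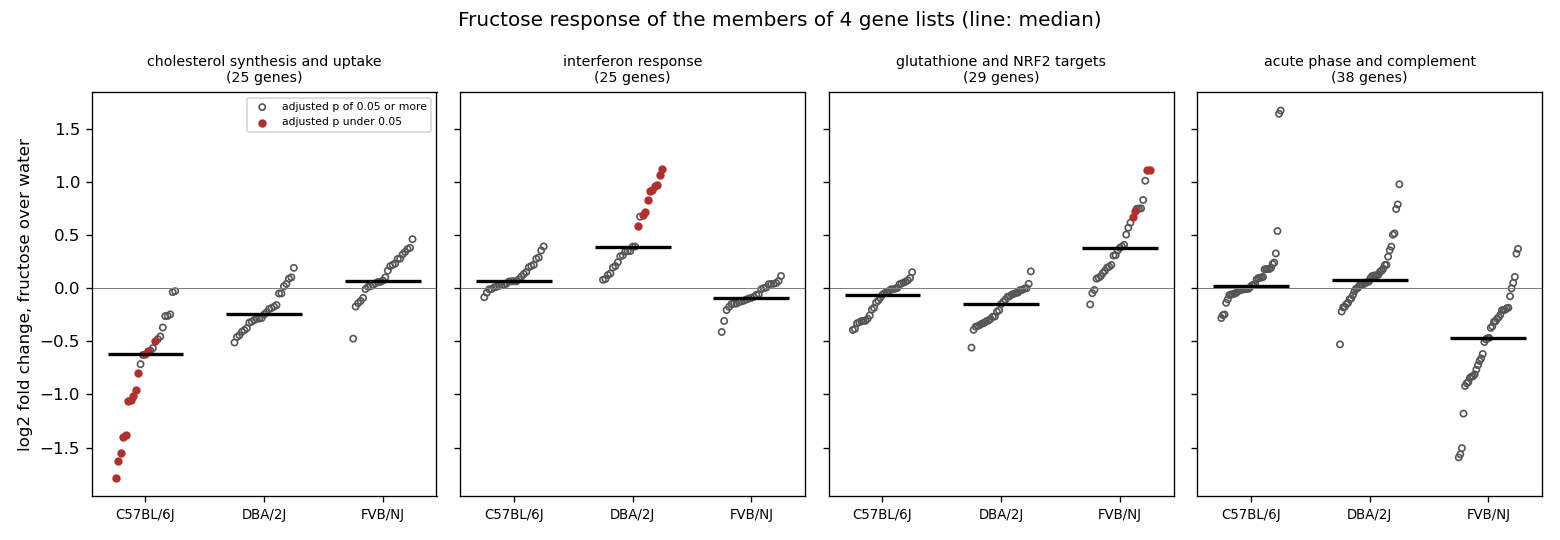
Log2 fold change, fructose over water (vertical axis), of each measured member of 4 gene lists in the 3 strains, filled where the adjusted p was under 0.05, with the median as a line. The cholesterol median was -0.62 in C57BL/6J, the interferon median 0.39 in DBA/2J, and the glutathione and acute phase medians 0.38 and -0.47 in FVB/NJ.

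Averaged over the strains, 9 genes rose and 27 fell, with 1054 at an unadjusted p under 0.05. Scd1 rose by 0.95 ± 0.20 (SE), the reticulon gene Rtn4 by 0.65 ± 0.13, Id3, an inhibitor of helix-loop-helix transcription factors, by 0.58 ± 0.12, the sulfotransferase gene Sult1c2 by 0.51 ± 0.11, Gabbr2 by 0.29 ± 0.06 and Apoc2 by 0.26 ± 0.06. The Scd1 response stood at -2.04 for C57BL/6J minus DBA/2J, so this average does not show a rise common to the strains. Mug-ps1 (-0.35 ± 0.07), Col4a1 (-0.26 ± 0.05), Tspan33 (-0.24 ± 0.05), Fam126a (-0.20 ± 0.04), Mri1, of methionine salvage (-0.19 ± 0.04), and Yipf3 (-0.18 ± 0.03) fell. The cholesterol list had a median of -0.28, with 7 genes that fell over all genes, 16 adjusted over the list alone, and adjusted p = 0.186 with an estimated correlation. The interferon list had a median of 0.18, with 0 genes passing over all genes in limma, 12 at an unadjusted p under 0.05, 8 adjusted over the list alone, and adjusted p = 0.431 with an estimated correlation. The acute phase list had a median of -0.10, and 0.01 without the 4 libraries that stood apart, at adjusted p = 0.7 with an estimated correlation. In all, 14 of 36 lists passed with the preset correlation, 7 without the 3 libraries richest in ribosomal RNA, and 0 passed camera with an estimated one, where 2 had an unadjusted p under 0.05. The count of genes was 10 without scaling (6 higher, 4 lower), 72 with array weights, and with limma 0 from FPKM (315 at an unadjusted p under 0.05) or with named genes scaled to a fixed total (1388). Left-out libraries moved it from 17 without C57BL/6J water replicate 4 to 59 without FVB/NJ water replicate 1, and without the 4 libraries that stood apart it was 17, with the calls of Rtn4, Id3, Gabbr2, Sult1c2 and Tspan33 lost.

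The water groups gave the differences between strains without fructose. At an adjusted p under 0.05 and a log2 difference of at least 1 in size, 208 genes were higher and 167 lower in DBA/2J than in C57BL/6J, 159 higher and 185 lower in FVB/NJ than in C57BL/6J, and 169 higher and 255 lower in FVB/NJ than in DBA/2J. Without the limit on size, 4684, 5177 and 4809 of the 9748 genes had an unadjusted p under 0.05 with limma for these pairs. Serpina3c, a serine protease inhibitor gene, was higher than in C57BL/6J by 6.93 ± 0.15 (SE) in DBA/2J and 6.37 ± 0.15 in FVB/NJ on the log2 scale. Rassf4 (4.05 ± 0.09), Corin (2.30 ± 0.08), Mup5 (5.96 ± 0.21) and Hddc3 (2.56 ± 0.10) were higher in DBA/2J than in C57BL/6J, and the histamine-forming enzyme gene Hdc (-2.70 ± 0.12) and Ttc38 (-2.08 ± 0.10) lower. Gdpd3 (4.28 ± 0.11) and Psmc3ip (1.98 ± 0.08) were higher in FVB/NJ than in C57BL/6J, and the ganglioside synthase gene B4galnt1 (-3.71 ± 0.07) and Hjurp (-2.55 ± 0.09) lower. Fgf21 was higher in DBA/2J than in C57BL/6J by 3.58 ± 0.38 (adjusted p 2.27e-09), and Scd1 was lower, at -2.56 ± 0.34 (adjusted p 2.77e-07).

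The interferon list was higher in DBA/2J than in C57BL/6J on water, with a median of 0.71, 18 of 25 genes higher over all genes by adjusted p alone (6 with a log2 difference of at least 1 as well), 19 adjusted over the list alone, and adjusted p = 0.57 with an estimated correlation. It was lower in FVB/NJ than in DBA/2J, with a median of -1.14, 23 genes lower over all genes by adjusted p alone (15 with that difference as well), 24 adjusted over the list alone, and adjusted p = 0.188 with an estimated correlation. Many genes outside the list differed in these pairs too (4684 and 4809 of all 9748 at an unadjusted p under 0.05 with limma). Ifi27 stood at -2.78 ± 0.11 in FVB/NJ minus DBA/2J, while Akr1b8 was higher by 1.67 ± 0.08. The MHC genes H2-K1 (-2.56 ± 0.08, DBA/2J minus C57BL/6J) and H2-T23 (-2.85 ± 0.08, FVB/NJ minus C57BL/6J) differ in sequence between strains, and the reference is that of C57BL/6J, so their values are uncertain. Reads of all strains were aligned to that reference. How far this affects other differences on water, those of Serpina3c and Mup5 included, was not tested. Rpl29 (-5.01 ± 0.06), Rpl21 (-4.00 ± 0.07) and Pttg1 (-3.31 ± 0.11) in DBA/2J minus C57BL/6J, Rps2 (-2.38 ± 0.09) and Abhd1 (3.39 ± 0.12) in FVB/NJ minus C57BL/6J, Rprl3 (7.46 ± 0.14 in DBA/2J and 8.35 ± 0.14 in FVB/NJ, against C57BL/6J) and BC021614 (6.43 ± 0.14, FVB/NJ minus C57BL/6J) have copies or neighbours, and their values are uncertain too. With the preset correlation 13, 10 and 8 lists passed for the 3 pairs, and with an estimated one camera passed 0 in each, with 1 list per pair at an unadjusted p under 0.05. Without scaling, FVB/NJ minus C57BL/6J had 716 higher and 74 lower genes and a median of all genes shifted by 0.46, and named genes scaled to a fixed total gave counts of 597, 574 and 656 for DBA/2J minus C57BL/6J, FVB/NJ minus C57BL/6J and FVB/NJ minus DBA/2J.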

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

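The tests with other assignments of diet or strain and the Gstp1 to Gstp2 ratio were chosen only after the results were seen, as were the error used for the macrophage list and the clock scores of DBA/2J and FVB/NJ.

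Cholesterol genes in C57BL/6J had a median log2 change of -0.62. A single library was argued against, since the median nearest to 0 with any of the 12 libraries left out was -0.48 (water replicate 3), and so was ribosomal RNA in water replicate 1 (-0.65 without it). A clock score was the mean log2 level of 6 clock genes minus that of 3 others. It differed by -0.0548 between diets (exact permutation p 0.799, 95% interval -0.467 to 0.357), within the bound set beforehand. This argues against a larger shift in clock phase or collection hour. How a smaller shift would move the cholesterol genes was not tested. Of 100 assignments 1, the real one, gave a list median as large in size (highest other 0.56) and as many genes over all genes tested (22, highest other 10). This share is the smallest that 100 assignments can give, and by it chance could be excluded for the count of genes. The list median was 1 of several set against these assignments after the results were seen. For that median, this share alone does not exclude chance. A response to fructose stays open as a hypothesis, found and tested on the same samples.

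Interferon genes in DBA/2J had a median of 0.39, which was 0.30 without water replicate 5, the value nearest to 0 with 1 library left out, and 0.38 without fructose replicates 10 and 11. These values argue against a single library and against ribosomal RNA as the cause. More macrophages stay open: their markers had a median of 0.11, which with its error between libraries reaches 0.205, above the bound of 0.196 set from the interferon median, whereas the smaller error over genes gives 0.132 and would exclude it; the first error was chosen after both were seen. Of 100 assignments 5 gave an interferon median as large (highest other 0.539), so chance could not be excluded for it. The clock score differed by 0.734 in DBA/2J (exact permutation p 0.117) and 0.379 in FVB/NJ (exact permutation p 0.245).

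Gstp1 and Gstp2 in FVB/NJ rose together. Without water replicate 2, which also held the acute phase transcripts, Gstp1 stood at 0.94, the value nearest to 0 with any 1 library left out, against a single library or that response as the whole cause. The log2 ratio of both genes varied 0.0908 times as much as Gstp1 itself, so reads shared between them may set their separate values. No other explanation was tested.

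Among 100 assignments the real count of genes was reached by 1 in DBA/2J (69; highest other 20), 3 in FVB/NJ (81; 311), 1, 2 and 2 for the differences C57BL/6J minus DBA/2J (46; 2), C57BL/6J minus FVB/NJ (24; 43) and DBA/2J minus FVB/NJ (35; 53), 1 for the joint test (77; 11), 1 for the average (36; 2) and 1 each for the strains on water (375, 344 and 424; 159, 163 and 214). By this share chance could be excluded in DBA/2J, for C57BL/6J minus DBA/2J, the joint test and the average. On water the other assignments mixed libraries of 2 strains, whose differences widened the spread, so lower counts there were likely in advance. In FVB/NJ and in both differences from FVB/NJ another assignment gave more genes than the real one. The FVB/NJ count was 9 without fructose replicate 18 and 1 in its 12 samples alone. For those 3 counts the share alone does not exclude chance. The C57BL/6J count was also 1 in its 12 samples alone. For C57BL/6J minus DBA/2J the count was 6 without C57BL/6J fructose replicate 12, so these counts too depend on the samples fitted. The 311 genes of another assignment in FVB/NJ exceed the real 81 and may point to a structure of the samples, which was not tested. The cholesterol median of -0.25 in DBA/2J was reached by 1 assignment, the real one (highest other 0.21 in size), the smallest share that 100 assignments can give. It was 1 of several list medians set against these assignments after the results were seen, so this share alone does not exclude chance. Of the list's members 0 passed in limma (5 at an unadjusted p under 0.05), and the list had adjusted p = 0.616 with an estimated correlation. Chance could not be excluded for the cholesterol median in FVB/NJ (0.07, reached by 51; highest other 0.28 in size) or the interferon medians in C57BL/6J (0.07, 58; 0.25) and FVB/NJ (-0.09, 10; 0.13). For the number of lists at the preset correlation, few assignments, the real one included, reached the real number in C57BL/6J (1; 18 lists, highest other 17), DBA/2J (3; 12, 13) and DBA/2J minus FVB/NJ (1; 21, 19). These shares were among many read after the results were seen, without adjustment. In each, another assignment came near the real number or passed it, so these shares alone do not exclude chance. Nor could it be excluded in FVB/NJ (13; 16, 19), C57BL/6J minus DBA/2J (19; 11, 16), C57BL/6J minus FVB/NJ (38; 12, 21), the average (15; 14, 19) or the strains on water (6, 62 and 91; 13, 10 and 8, highest others 14, 22 and 20). Other assignments passed a median of 9 lists in C57BL/6J, 6 in DBA/2J, 9 for DBA/2J minus FVB/NJ and 11 in FVB/NJ. Many of the lists that passed may therefore owe nothing to fructose. With an estimated correlation 1 list passed in C57BL/6J, 1 in DBA/2J and 0 for DBA/2J minus FVB/NJ.

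Single samples lay far from the rest of their group in 14 of 126 checks, where chance gives 6.3, by the share of the range that separates them (Dixon's criterion). In C57BL/6J water replicate 1 these were the named share (0.630) and Rn45s (0.899), in DBA/2J water replicate 2 the named share (0.660) and Rn45s (0.822), and in DBA/2J fructose replicate 10 Rn45s (0.675). C57BL/6J water replicate 3 was high in the cholesterol list (0.768), Sqle (0.799), Msmo1 (0.654) and Fdps (0.743), and water replicate 6 in Apoc2 (0.654). FVB/NJ water replicate 2 was high in the acute phase list (0.824) and low in the glutathione list (0.732), fructose replicate 10 was high in Mup20 (0.641), and DBA/2J water replicate 5 was low in Ccdc117 (0.6254).

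The tests of the difference itself passed for 46, 24 and 35 genes and jointly for 77. C57BL/6J minus DBA/2J gave Tfrc 1.19, Slc16a5 1.16, Tra2b 0.98, Hacl1 0.98, Scd1 -2.04, Snhg12 -0.82, Trex1 -0.66, Scpep1 -0.53 and Rassf8 -0.44. C57BL/6J minus FVB/NJ gave Urad 1.21, Sec13 0.55, Copg1 0.44, Idi1 -2.16, Msmo1 -2.01, Csad -1.68, Gstp1 -1.42 and Gstp2 -1.42. DBA/2J minus FVB/NJ gave Apol9a 1.26, Gbp11 1.21, Trex1 0.67, Parp9 0.56, Zc3hav1 0.43, Mup20 -1.60, Gstp1 -1.47, Gstp2 -1.46, Gstm4 -1.03 and Htatip2 -0.82.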

How the results depend on the processing

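Leaving out the 3 libraries richest in ribosomal RNA or the 4 that stood apart, scaling named genes to a fixed total, the named share as a covariate, the lane 8 file of FVB/NJ water replicate 9 not used and shared numbers without the block were chosen after seeing the data. Over the alternatives other than single libraries left out, named genes that had passed kept direction and call in 1710 cases, lost the call in 448 and reversed in 2. These cases pool the fructose comparisons with genes named for the strains on water, which lost no call in any alternative. Every loss and reversal was in a fructose comparison, so the fructose calls were less stable than the pooled numbers. Named genes that had not passed stayed so in 1317 cases and passed in 8. Lists that had passed kept the call in 704 cases, lost it in 238 and reversed in 3. Over all alternatives, single libraries included, the calls lost most often were those of Mup20 for DBA/2J minus FVB/NJ (44 of 54) and of Acaca (43 of 54), Mir7225 (42 of 55) and Csad (41 of 55) in FVB/NJ. Without that lane 8 file the counts of genes were 22, 68 and 75 within strains, 46, 23 and 26 for the differences, 30 for the average and 74 jointly. The calls of Rassf8, Gbp11 and Mup20 for differences and of the ribosomal list in FVB/NJ were lost. The cause was not tested except where a filter or fewer samples changed what was fitted. Depth is known only as implied bases, so limits for weak genes were not set.

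Counts of genes follow for C57BL/6J, DBA/2J and FVB/NJ (22, 69 and 81), C57BL/6J minus DBA/2J, C57BL/6J minus FVB/NJ and DBA/2J minus FVB/NJ (46, 24 and 35), the average (36), the joint test (77), and DBA/2J minus C57BL/6J, FVB/NJ minus C57BL/6J and FVB/NJ minus DBA/2J on water (375, 344 and 424). Without scaling they were 13, 24 and 9, then 88, 7 and 2, 10 for the average, 35 jointly and 790 for FVB/NJ minus C57BL/6J on water. Of these calls 76.9%, 20.8%, 88.9%, 100%, 85.7%, 0% and 60% were higher within strains, for the differences and for the average. The shares were 9.09%, 60.9%, 54.3%, 60.9%, 20.8%, 60% and 25% with scaling. On water they were 80.4%, 90.6% and 61.4% without scaling and 55.5%, 46.2% and 39.9% with it. The median of all genes then moved by 0.32, -0.22, 0.01, 0.54, 0.30, -0.23 and 0.04, and by 0.27, 0.46 and 0.19 on water. Scpep1 became 0.0892 and Rassf8 0.16 for C57BL/6J minus DBA/2J, where 18 lists passed. FPKM without scaling gave limma counts of 0, 11 and 5, then 3, 0 and 2, 0 for the average and 6 jointly (684, 481 and 315 at an unadjusted p under 0.05 where the count was 0). The share higher was 27.3%, 100% and 100% in DBA/2J, FVB/NJ and C57BL/6J minus DBA/2J, 0% for DBA/2J minus FVB/NJ, and 69.5%, 68.3% and 44.2% on water. The median of all genes shifted by 0.14, -0.10, 0.02, 0.25, 0.12, -0.12 and 0.02, then 0.15, 0.19 and 0.04. Named genes scaled to a fixed total gave 8, 31 and 27, then 7, 10 and 4, 0 for the average in limma (1388 unadjusted), 8 jointly and 597, 574 and 656 on water. Within strains and for the differences 37.5%, 74.2%, 66.7%, 85.7%, 40% and 50% were higher. Quantile normalization gave 40% higher for C57BL/6J minus DBA/2J, 8 lists for DBA/2J minus C57BL/6J on water, and a ribosomal list median of -0.0101 in FVB/NJ.

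Array weights gave 69, 354 and 27, then 435 and 56, 72 for the average and 310 jointly. Fits of 12 samples alone gave 1, 118 and 1. No filter gave 109 in DBA/2J, then 16, 11 and 15, 4 for the average and 35 jointly. A mean TPM of at least 5 gave 18 in DBA/2J, 25 and 16 for DBA/2J differences from C57BL/6J and FVB/NJ, 14 for the average and 248, 223 and 263 on water. A single lane gave 29 in FVB/NJ, 14 and 21 for the same differences and 8 for the average. A pseudocount of 0.1 gave 29 and 14 for them and 537 for FVB/NJ minus C57BL/6J on water, and a pseudocount of 5 gave 188, 148 and 185 on water. TPM above 0 in all samples gave 21 and summed coverage 16 for DBA/2J minus FVB/NJ, and summed coverage 592, 553 and 649 on water. The named share as covariate gave 10 for C57BL/6J minus DBA/2J. Without the 3 libraries richest in ribosomal RNA the counts were 45 in DBA/2J, then 7, 12 and 14, 5 for the average and 33 jointly, with 7 lists in DBA/2J and 7 for the average. Without the 4 libraries they were 24 in FVB/NJ, then 8, 14 and 20, 17 for the average and 41 jointly, with 6 lists in FVB/NJ, a fatty acid oxidation median of -0.0324 there and an acute phase median of 0.00672 for the average. With an estimated correlation 1, 1 and 0 lists passed within strains, 0, 1 and 0 for the differences, 0 for the average and 0, 0 and 0 on water. In camera 4, 2, 3, 5, 3, 8, 2, 1, 1 and 1 had an unadjusted p under 0.05.

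Sample numbers shared by C57BL/6J and DBA/2J did not pair the samples: same-numbered samples had a mean correlation of -0.0017 (-0.338 to 0.258 over 10 pairs). With the replicate block 9 genes differed in response against 69 among the same samples without it, and 370 against 373 on water.

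With 1 library left out, counts ran from 11 to 32 in C57BL/6J, 35 to 106 in DBA/2J, 9 to 164 in FVB/NJ, 6 to 114, 10 to 86 and 14 to 41 for the differences, 17 to 59 for the average, 25 to 148 jointly, and 352 to 401, 327 to 365 and 406 to 441 on water. Named genes that had passed kept the call in 3782 cases and lost it in 502, and those that had not passed stayed so in 2504 and passed in 16. Here too, all losses were in fructose comparisons and none among the genes named on water. For C57BL/6J minus DBA/2J the count was 12, 6, 15, 28 and 6 without C57BL/6J fructose replicates 10, 12, 13, 14 and 15. It was 17, 11, 9, 7 and 107 without water replicates 1, 2, 4, 5 and 6. For the same difference it was 6, 13 and 21 without DBA/2J fructose replicates 11, 13 and 14, 17, 7 and 16 without DBA/2J water replicates 2, 4 and 5, and 114 without FVB/NJ water replicate 2. For C57BL/6J minus FVB/NJ it was 37 and 10 without C57BL/6J fructose replicates 11 and 13, and 40, 15, 14, 12 and 56 without water replicates 2, 3, 4, 5 and 6. It was 51, 37, 10, 13 and 10 without FVB/NJ fructose replicates 10, 12, 18, 5 and 6, and 15, 86 and 50 without FVB/NJ water replicates 17, 1 and 9. For DBA/2J minus FVB/NJ it was 21, 20, 20, 21 and 20 without C57BL/6J fructose replicates 10, 12 and 13 and water replicates 2 and 4. Counts of 15, 16, 17, 14 and 17 followed without DBA/2J fructose replicates 11 and 13 and water replicates 2, 4 and 5. They were 21, 23, 21, 20, 18, 16 and 22 without FVB/NJ fructose replicates 10, 12, 18, 5 and 6 and water replicates 15 and 17. The average gave 19, 23, 21 and 17 without C57BL/6J fructose replicates 10, 12 and 13 and water replicate 4. It gave 22, 18 and 20 without DBA/2J fructose replicate 13 and water replicates 5 and 6, and 59 without FVB/NJ water replicate 1. The joint test gave 40, 38, 25, 44, 45, 30 and 148 without C57BL/6J fructose replicates 10, 12 and 13 and water replicates 1, 4, 5 and 6. It gave 29, 30 and 48 without DBA/2J fructose replicate 11 and water replicates 4 and 5, and 44, 38 and 145 without FVB/NJ fructose replicates 18 and 6 and water replicate 1.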

Other observations

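The lists were fixed first, but the values in this part were all chosen after they were seen. Counts of list members here use the adjusted p alone, and those with a log2 difference of at least 1 as well follow each. The lists had 29 (unfolded protein response), 30 (urea cycle), 16 (MHC), 15 (Kupffer cell) and 44 (fatty acid oxidation) measured genes. Of all 9748 genes, 4684 (DBA/2J minus C57BL/6J), 5177 (FVB/NJ minus C57BL/6J) and 4809 (FVB/NJ minus DBA/2J) had an unadjusted p under 0.05 with limma. Many members of any list are therefore likely to differ on water. On water, the unfolded protein response list was higher in DBA/2J than in C57BL/6J, with a median log2 difference of 0.50, 21 genes higher and 1 lower (8 and 1 with that difference), 21 higher adjusted over the list alone, and adjusted p = 0.57 with an estimated correlation. The endoplasmic reticulum chaperone gene Hspa5 stood at 1.12 ± 0.18 (SE) and the stress transcription factor gene Ddit3 at 1.02 ± 0.17. The urea cycle list was lower in the same pair (median -0.56, 18 genes lower and 1 higher, 7 and 0 with that difference, 19 lower adjusted over the list alone, adjusted p = 0.57 with an estimated correlation).

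In FVB/NJ minus C57BL/6J on water, the fatty acid translocase gene Cd36 stood at -1.95 ± 0.20 (adjusted p 1.37e-09). The MHC list had a median of -0.92 (12 genes lower, 7 with that difference, 2 higher, 0 with it, and 13 lower adjusted over the list alone) and the Kupffer cell list -0.44 (9 lower, 0 with that difference, 9 adjusted over the list alone), both at adjusted p = 0.707 with an estimated correlation. MHC genes differ in sequence between strains and the reference is that of C57BL/6J, so the values of that list are uncertain. In FVB/NJ minus DBA/2J the fatty acid oxidation list had a median of -0.48 (31 lower and 1 higher, 14 and 0 with that difference, 32 lower adjusted over the list alone, adjusted p = 0.734 with an estimated correlation).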
